A study of Mustela putorius furo with 2 samples.

How the data were processed

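The series holds single-cell RNA sequencing of the dorsal cortex of wild-type ferret pups at postnatal day 3, made as 2 replicates of 1 group. Per the labels, the tissue was dissociated with papain, the libraries were built on the 10x Genomics Chromium platform, and sequencing was on an Illumina HiSeq. The deposited file is 1 matrix of whole-number UMI counts per gene and cell for both replicates together, so its unit is counts and it carries no normalization. The counts come from Cell Ranger, per the submitters' processing notes; its version and the genome build are not given in the sources used here. The matrix held 14787 cells, 60743615 UMIs and 29816 gene names. UMIs were found for 21317 names, the last of them at position 22008, and the 7808 names after it, among them human names such as GFAP and MALAT1, held none and were treated as unmeasured. Of the names with a UMI, 21231 (99.6%) matched a gene symbol of the RefSeq annotation of ferret assembly ASM1176430v1.1, which was used only to match names and to find 13 mitochondrial genes. No positions are given for genes because the build behind the counts is not given.

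The barcodes carried 2 suffixes, and only 21 barcode sequences occurred under both, so the suffixes were read as the 2 libraries and are called library A (9782 cells) and library B (5005 cells). The labels do not say which suffix belongs to which replicate, nor whether the 2 replicates are separate animals. The p-values therefore rest only on how the differences between classes vary across these 2 samples, pooled over genes as given below. That spread may be technical. No cell in the deposited matrix had fewer than 1501 UMIs or more than 4995 genes, so cells had been filtered before deposit, by thresholds that are not given in the sources used here.

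Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which removed 14 cells. Doublets were called with Scrublet in scanpy 1.11.5 in each library, which marked 1 cell in library A (0.0102%) and 0 cells in library B and removed that cell. So low a share means that the automatic threshold did not separate doublets. Clusters with a mean doublet score above 0.15 were therefore left unnamed, and removal of the 496 cells with a score above 0.2 was added as an alternative. In all, 14772 cells remained.

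Each gene was used either to make the clusters or to test them. The 156 measured class markers and a seeded random set of the other genes (10471 of them) made the clusters. The remaining genes (10472) and the 218 measured genes of the fixed lists were held out and tested. Counts were scaled to 10000 per cell and log-transformed, the 2000 most variable clustering genes gave 30 principal components, and a graph of 20 neighbours was clustered with leidenalg 0.10.2 at resolution 1. Clusters whose best marker list was of radial glia, gliogenic progenitors, astrocytes or oligodendrocyte precursors held 3665 cells. These were clustered again without 556 genes that followed the cell cycle lists (r above 0.15), for 28 final clusters. A cluster took a class name when at least 3 markers were 1.5-fold or more above the other cells at 10 CPM or more and the mean log2 ratio of its list led that of the next class by 0.25. CPM is the usual scaling of a gene's UMIs by the total UMIs of the summed cells. All names end in "-like" because they rest on marker RNA alone. Class markers are not reported as results of any comparison.

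The cell filters, the marker lists, the gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The naming thresholds and the second round of clustering were settled after clusters and marker tables had been seen but before any test result was seen. The planned comparisons of truncated with outer radial glia and of astrocytes with radial glia were left out because no cluster carried those names by the thresholds. This depends on the settings: with no cell filter, clusters named astrocyte-like (564 and 257 cells, those found again as CLU-high glia) and radial glia-like (426 and 233) were present, and with the stricter filter likewise (624 and 282, then 383 and 222). With the called doublet kept, the cluster found again as CRYAB-high glia was named radial glia-like (274 and 156 cells), and with the other random set of clustering genes a cluster was named astrocyte-like (57 and 32 cells). The comparison of astrocytes with radial glia was not run on those clusters. The left-out comparisons were replaced, after the clusters were seen, by comparisons of 3 unnamed glial clusters called by their leading marker: CRYAB-high with CLU-high glia and LIFR-high with CLU-high glia. Both use the same CLU-high cells.

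For each comparison, UMIs were summed per class and library into 4 sums, with at least 20 cells in each. Cells were never treated as replicates. The sums were fitted in R 4.3.3 with edgeR 4.0.16 (TMM scaling, filterByExpr, library as a block), which leaves 1 residual degree of freedom. The prior degrees of freedom of the fit were infinite in the first 3 comparisons below, so a gene's own spread between the libraries had no weight there and a spread shared by the genes set each p; they were 14.6 in the last. Very small p-values rest on this shared spread. Genes were tested with its quasi-likelihood F test, two-sided, and adjusted with the Benjamini-Hochberg method over all held-out genes that passed the filter, at a threshold of 0.05. The standard error (SE) is the log2 fold change divided by the square root of F. The common dispersion was 0.000716, 0.00288, 0.00471 and 0.00329 in the order of the 4 comparisons below. The clusters and the tests used the same cells, so held-out genes that vary together with clustering genes were more likely to be called than in independent groups. On simulated counts of the same depth, in the same order, the test recovered 74.0%, 63.3%, 45.9% and 69.7% of 2-fold changes and 100%, 96.0%, 91.8% and 99.0% of log2 changes of 2. The false share among its calls was 7.94%, 3.66%, 2.90% and 5.08%. The simulation used the spread that the same fit had estimated, changed far fewer genes than were called here and held no clustering step. Its recovered and false shares are therefore not rates for the calls reported below.

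The 17 lists tested were FGF and ERK targets, BMP signalling, hedgehog signalling, Notch signalling, Wnt signalling, YAP and TAZ targets, LIF receptor and STAT3 signalling, gliogenic transcription factors, neuronal differentiation, astrocyte transport, extracellular matrix, cholesterol synthesis, glycolysis, fatty acid oxidation, S phase, G2 and M phase, and immediate early and dissociation response genes. List members were counted by the test adjusted over all genes and again adjusted over the list alone. Named genes are the 10 with the largest log2 fold change in each direction among those past the threshold, with the same direction in both libraries and at least 50 CPM in the higher class, and up to 4 members of each list with the smallest p. A few of these genes are not reported here. For genes with 1 to 3 UMIs in the lower class, the ratio of CPM with its exact 95% counting interval is given in place of the fitted value. Shares of cells carry exact Clopper-Pearson 95% intervals, which cover counting error only.

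Alternatives covered the cell filter, doublets, the clustering genes and resolution, the scaling, the test (DESeq2 1.42.0), the low-count filter, the replicate block, fits of all classes together, every cell thinned to 1500 UMIs, and each library left out. An unnamed cluster was taken as found again under another clustering when the Jaccard index of its cells with the original was at least 0.5. Computation was in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.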

Results

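Single-cell RNA was measured in dorsal cortex of ferret pups at postnatal day 3, in 2 replicate libraries of 1 wild-type group. There was no second condition, so every comparison here is between cell classes within the 2 libraries (n = 2 libraries throughout). Library A held 41836475 UMIs in 9782 cells, with a median of 3602.5 UMIs (range 1501 to 16955) and 1879 genes per cell. Library B held 18907140 UMIs in 5005 cells, with a median of 3068 UMIs (range 1501 to 16295) and 1667 genes per cell. The median mitochondrial share was 1.20% in library A and 1.49% in library B.

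Neurons of the excitatory lineage were the largest class. Excitatory neuron-like cells made up 44.9% of the 9779 kept cells of library A (95% interval 43.9 to 45.9) and 40.0% of the 4993 of library B (38.6 to 41.3). Neuronal intermediate progenitor-like cells, which carried EOMES (mean 425 CPM) and NEUROG2 (133 CPM), made up 17.6% (16.9 to 18.4) and 15.96% (15.0 to 17.0). Inhibitory neuron-like cells, with DLX1 at 909 CPM and DLX5 at 479 CPM, made up 11.1% (10.5 to 11.7) and 6.47% (5.80 to 7.19).

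Of the cells clustered again, a cluster of 294 cells and one of 141 cells stayed unnamed without a high doublet score. The first had HOPX as its leading class marker and mitotic leading genes. Apart from these clusters, glia and their progenitors were described in 5 classes. The largest, CLU-high glia, took 7.42% of library A (6.91 to 7.96) and 6.97% of library B (6.28 to 7.71). It carried the outer radial glia markers HOPX (1074 CPM) and PTPRZ1 (1092 CPM) together with the astrocyte markers CLU (587 CPM), APOE (1021 CPM) and AQP4 (213 CPM). CRYAB-high glia, led by the truncated radial glia marker CRYAB (289 CPM), took 1.72% (1.47 to 1.996) and 2.16% (1.78 to 2.61). LIFR-high glia, with LIFR (323 CPM) as the leading class marker, took 0.839% (0.667 to 1.04) and 0.841% (0.607 to 1.14). The stress-response genes JUNB, CEBPD and GADD45B stood ahead of LIFR among the 10 leading genes of this cluster. CLU-high and LIFR-high glia were not named further because their markers pointed to more than 1 class. In CRYAB-high glia the truncated radial glia list led (mean log2 ratio 0.974), but only 1 of its 5 markers was higher. Of 10 radial glia markers 2 were higher (0.373), so neither list reached the 3 markers needed for a name. The deep-layer neuron list had 3 of 8 markers higher but did not lead (0.26). The word glia in the name of this cluster thus rests on few glial markers. Gliogenic progenitor-like cells, with EGFR at 1014 CPM and OLIG1 at 1293 CPM, took 2.78% (2.46 to 3.13) and 2.38% (1.98 to 2.85). Their leading genes also held DLX1, DLX2 and GSX2, transcription factor genes of the ventral forebrain. Oligodendrocyte precursor-like cells, with PDGFRA at 559 CPM and SOX10 at 163 CPM, took 1.55% (1.32 to 1.82) and 1.20% (0.918 to 1.54). All 5 measured markers of committed oligodendrocytes were also higher in them (mean log2 ratio 3.11, beside 3.50 for the precursor list). The 2 lists counted as 1 class in the naming.

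Endothelial-like, erythroid-like and ependymal-like cells took a larger share of library B than of library A. Endothelial-like cells took 2.16% of library A (1.88 to 2.47) and 10.9% of library B (10.0 to 11.8). All 6 endothelial markers were higher in them (mean log2 ratio 5.195), but so were 5 of 5 mural (2.682) and 4 of 5 fibroblast markers (2.255). The class may therefore hold mural or fibroblast RNA or cells. Erythroid-like cells took 2.02% (1.75 to 2.32) and 3.69% (3.18 to 4.25), but 7 of 7 microglia markers were higher in them (mean log2 ratio 3.14) beside 3 of 5 erythroid markers (3.93), so the name is uncertain. Microglia-like cells took 0.450% (0.327 to 0.604) and 0.601% (0.406 to 0.857), and mural-like cells 0.143% (0.0783 to 0.240) and 0.180% (0.0825 to 0.342). Ependymal-like cells were 6 of the kept cells of library A (0.0614%, 0.0225 to 0.134) and 46 of those of library B (0.921%, 0.675 to 1.23). The remaining clusters stayed unnamed, among them 3 with a high doublet score and 1 of 249 cells led by the interneuron peptide gene SST. With a resolution of 2, neuronal intermediate progenitor-like cells took a mean of 7.58% of the libraries in place of 16.8%, microglia-like cells 3.02% in place of 0.525% (205 and 197 cells in place of 44 and 30), and erythroid-like cells 1.01% in place of 2.86% (40 and 80 cells in place of 198 and 184).

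**Figure D1:**
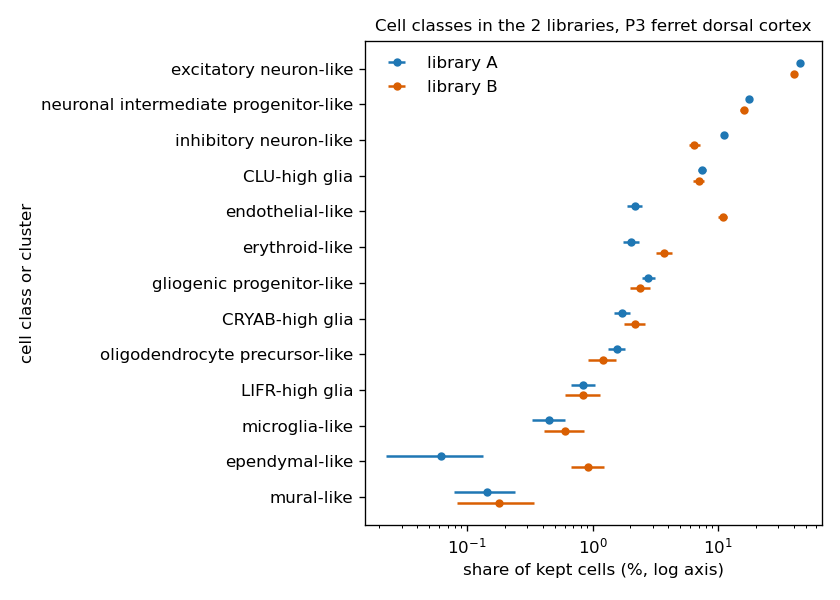
Share of kept cells in each of the 13 classes, in percent on a log axis, for library A (9779 cells) and library B (4993 cells); bars are exact 95% intervals for counting error only. Endothelial-like cells took 2.16% of library A and 10.9% of library B, while LIFR-high glia took 0.839% and 0.841%. Unnamed clusters other than CLU-high, CRYAB-high and LIFR-high glia are not drawn.

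The series title sets neurogenic against gliogenic lineages, and the first comparison was of gliogenic progenitor-like cells (272 and 119 in libraries A and B) with neuronal intermediate progenitor-like cells (1724 and 797). Gliogenic progenitor-like cells held far more RNA of CD9, a tetraspanin (log2 fold change 5.53, SE 0.29, adjusted p = 3.65e-78), and of BCAN, which encodes the matrix proteoglycan brevican (3.29, SE 0.21, adjusted p = 2.44e-54). GSX2, a homeobox gene of ventral forebrain progenitors, was higher by 4.59 (SE 0.23, adjusted p = 2.17e-83), with 4.25 in library A alone and 5.77 in library B alone. Neuronal intermediate progenitor-like cells held more ROBO1, an axon guidance receptor gene (-3.43, SE 0.09, adjusted p = 1.55e-295), and more GAP43, a growth cone gene (-3.06, SE 0.16, adjusted p = 1.15e-78). Of 5941 genes tested, 739 were higher and 934 lower in gliogenic progenitor-like cells, and 1648 of the called genes had the same direction in both libraries. The differences exceeded 2-fold for 306 of the higher and 385 of the lower genes. Here and below, gene values are log2 fold changes of the first class over the second, with adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

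Also higher in gliogenic progenitor-like cells were RTP5 (5.08, SE 0.23), the sorting nexin gene SNX22 (3.97, SE 0.27), CUNH11orf96 (3.47, SE 0.13) and the kinase gene STK32A (3.41, SE 0.25). Also higher were SPATA6 (3.26, SE 0.23), the toll-like receptor 4 interactor gene TRIL (3.22, SE 0.21) and the leucine zipper gene LUZP2 (3.21, SE 0.08). Lower were the teneurin gene TENM4 (-4.12, SE 0.16; -3.46 in library B alone), SHISAL1 (-4.005, SE 0.33), TNFAIP8 (-3.74, SE 0.17; -4.36 in library B alone), and CCSER1 (-3.56, SE 0.15). Further lower genes were ARHGAP20 (-3.42, SE 0.18; -2.81 in library B alone), the cadherin gene CDH8 (-3.16, SE 0.21; -3.82 in library B alone) and TAFA2 (-2.89, SE 0.18). The plot of 19 of the genes with the largest differences shows the fitted value and both libraries.

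**Figure D2:**
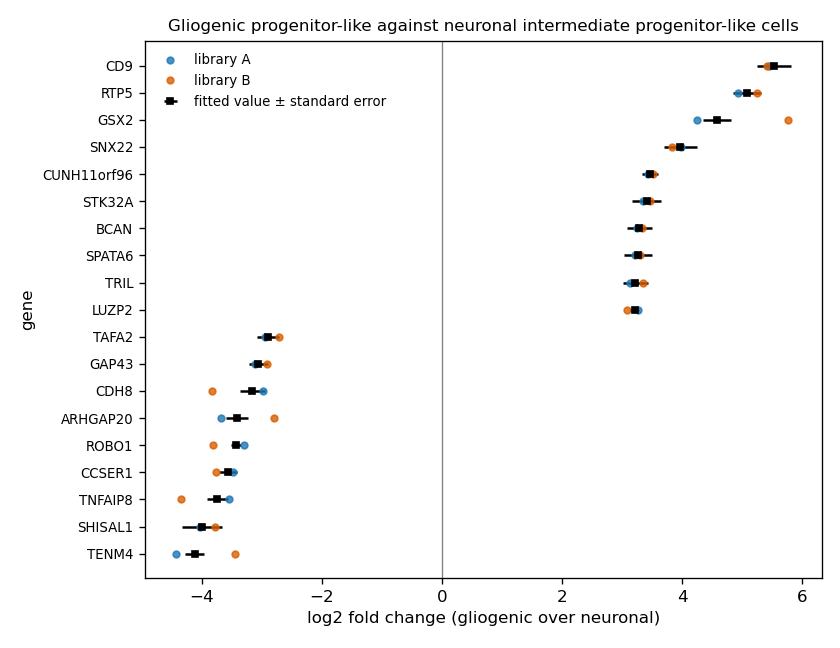
Log2 fold change of 19 genes in gliogenic progenitor-like over neuronal intermediate progenitor-like cells; black squares are fitted values with their standard error, blue and orange points are libraries A and B. All 19 lie on the same side of 0 in both libraries, which was a condition for a gene to be plotted. Fitted values run from CD9 at 5.53 to TENM4 at -4.12.

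Among signalling lists, FGF and ERK targets stood higher in gliogenic progenitor-like cells: 9 of 11 tested members rose and 1 fell, also adjusted over the list alone. ETV1 rose by 3.02 (SE 0.10), SPRY2 by 2.48 (SE 0.16) and ETV5 by 2.47 (SE 0.12; 3.06 in library B alone), transcriptional targets and a feedback inhibitor of FGF signalling. Of 11 BMP signalling genes, 5 rose and 2 fell (6 and 2 adjusted over the list alone), with BMP2 at 3.88 (SE 0.35; 3.21 in library B alone), BMP7 at 1.72 (SE 0.22) and the inhibitory gene SMAD7 at -2.07 (SE 0.34; -2.91 in library B alone). Hedgehog genes went both ways, with 3 of 7 higher and 2 lower (the same counts adjusted over the list alone). The receptor genes GAS1 and PTCH1 rose by 2.06 (SE 0.07) and 1.59 (SE 0.24), and GLI2 fell by 0.88 (SE 0.12). Of 9 Notch genes 4 rose and 1 fell, and of 8 Wnt genes 4 rose and 0 fell (4 and 1, then 5 and 0, adjusted over the list alone). The ligand gene DLL1 rose by 1.83 (SE 0.12), TCF7L2 by 1.87 (SE 0.23) and TCF7L1 by 2.16 (SE 0.29). Of 10 YAP and TAZ targets 3 rose and 2 fell (5 and 2 adjusted over the list alone). Of 7 LIF receptor and STAT3 genes 1 rose, CNTFR (0.64, SE 0.23, adjusted p = 0.0252), the same count adjusted over the list alone. DESeq2's Wald test and 6 other alternatives ended that call.

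All 13 neuronal differentiation genes tested were called, 11 lower and 2 higher in gliogenic progenitor-like cells, also adjusted over the list alone. STMN2 was at -1.75 (SE 0.07), ROBO2 at -1.65 (SE 0.05) and the transcription factor gene SOX11 at -1.495 (SE 0.07). Of 7 gliogenic transcription factor genes 2 rose, SOX8 (1.70, SE 0.15) and SALL3 (1.65, SE 0.13), and 4 fell, among them LHX2 (-0.86, SE 0.09) and NFIB (-0.66, SE 0.05), also adjusted over the list alone. Astrocyte transport genes were higher in 5 of 9 cases and lower in 0, with the potassium channel gene KCNJ10 at 2.15 (SE 0.33) and the glutamine synthetase gene GLUL at 0.76 (SE 0.10). Extracellular matrix genes were higher in 5 of 8 and lower in 1, with CSPG5 at 3.01 (SE 0.23; 3.64 in library B alone), ITGB8 at 1.11 (SE 0.10) and VCAN at 1.06 (SE 0.11). Cholesterol synthesis genes were higher in 4 of 15 and lower in 0, all by less than 2-fold, with NSDHL at 0.99 (SE 0.31) and FDPS at 0.37 (SE 0.09), and DESeq2 ended all 4 calls. Glycolysis genes were lower in 5 of 12 and higher in 1, with GPI at -1.20 (SE 0.12), TPI1 at -0.73 (SE 0.10) and LDHB at 0.56 (SE 0.05). Fatty acid oxidation genes were lower in 1 of 9, ACADVL (-0.35, SE 0.12, adjusted p = 0.0107), and higher in 0, a call that DESeq2 ended. The counts of these 5 lists stayed the same adjusted over the list alone. With a resolution of 0.5, TPI1 and ACADVL came to 0.0023 and 0.0070.

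Immediate early genes were higher in gliogenic progenitor-like cells in 6 of 13 cases and lower in 1 (7 and 1 adjusted over the list alone), with FOS at 1.86 (SE 0.07) and EGR1 at 1.78 (SE 0.09). These genes also respond to tissue dissociation, and the mean mitochondrial share was 1.64% in gliogenic progenitor-like cells and 1.18% to 1.24% in the clusters of neuronal intermediate progenitor-like cells. Cell cycle genes gave no stable direction. Of 19 S phase genes 12 were higher and 0 lower, with PCNA at 0.57 (SE 0.07) and TYMS at 0.48 (SE 0.09), with the same counts adjusted over the list alone. Of 22 G2 and M phase genes 2 were higher and 1 lower, also adjusted over the list alone. The lower gene, CDC20 (-0.40, SE 0.13), was at -0.59 in library A alone and 0.051 in library B alone. A further setting used only the neuronal intermediate progenitor-like cells among the 3665 cells clustered again, here called the dividing compartment. Those 3665 cells were picked by glial marker lists and not by division. The setting dropped a cluster of 1553 neuronal intermediate progenitor-like cells. With it, 0 S phase genes were higher and 12 lower, and 0 G2 and M phase genes higher and 21 lower. PCNA was then at -0.27 and TYMS at -0.34. With cells of a doublet score above 0.2 removed, 20 G2 and M phase genes were higher and 0 lower.

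The count of genes in this comparison depended on the test and on depth. DESeq2's Wald test called 245 genes higher and 265 lower, and with every cell thinned to 1500 UMIs edgeR called 266 and 442. Neither ended the call of any of the 19 plotted genes that it tested.

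The second comparison was between CRYAB-high glia (168 and 108 cells) and CLU-high glia (726 and 348 cells). Against the other cells clustered with them, CLU-high glia were higher in 7 of 9 astrocyte and 8 of 10 radial glia markers, and CRYAB-high glia in 1 of 5 truncated radial glia, 2 of 10 radial glia and 3 of 8 deep-layer neuron markers. CRYAB-high glia held more IGFBP5, an insulin-like growth factor binding protein gene (2.87, SE 0.17, adjusted p = 1.15e-59). They held less of SLC6A11, the gene of the GABA transporter GAT3 (-3.26, SE 0.32, adjusted p = 1.81e-22; -2.49 in library B alone), SLC38A3, a glutamine transporter gene (-2.44, SE 0.23, adjusted p = 5.17e-24), and HEY1, a Notch target gene (-2.44, SE 0.26, adjusted p = 3.13e-18). Of 5428 genes tested, 287 were higher and 489 lower, 147 and 185 of them by more than 2-fold, and 775 of the called genes had the same direction in both libraries.

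Mitotic genes were prominent among the genes higher in CRYAB-high glia: CCNB1 (2.54, SE 0.25), CENPF (2.02, SE 0.17), BIRC5 (1.99, SE 0.17) and PTTG1 (1.88, SE 0.19). Other genes among the largest rises were NELL2 (2.37, SE 0.17), the calmodulin-binding gene PCP4 (2.21, SE 0.19; 1.36 in library B alone) and NKAIN3 (1.92, SE 0.27). The adhesion gene DSCAML1 (1.90, SE 0.28) and the ion exchanger gene SLC24A3 (1.89, SE 0.17) also rose. The largest falls, besides the transporters above, were LUZP2 (-2.40, SE 0.12), the amino acid transporter gene SLC7A10 (-2.28, SE 0.27), the potassium channel gene KCNJ15 (-2.08, SE 0.17; -3.46 in library B alone; call ended by DESeq2), and RGS7 (-2.07, SE 0.15). They were followed by ACBD7 (-1.97, SE 0.11), PARM1 (-1.91) and ANOS1 (-1.89).

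Of 21 G2 and M phase genes 20 were higher in CRYAB-high glia and 0 lower (21 and 0 adjusted over the list alone), with UBE2C at 1.77 (SE 0.16) and TOP2A at 1.53 (SE 0.15). An unnamed cluster of 294 cells, whose leading genes were mitotic ones such as CDC20, CCNB1 and CCNB2, was part of neither side, so this count depends on where its cells are placed. Of 19 S phase genes 0 were higher and 4 lower (0 and 5 adjusted over the list alone), with PCNA at -0.53 (SE 0.14; call ended by DESeq2). With the single called doublet kept, the clusters were drawn differently (Jaccard index 0.583 for CRYAB-high glia). In that setting 9 S phase genes were higher and 0 lower, and PCNA was at 0.51. Cholesterol synthesis genes were lower in 13 of 15 cases and higher in 0 (14 and 0 adjusted over the list alone), with HMGCS1 at -1.35 (SE 0.12), FDPS at -1.26 (SE 0.11) and IDI1 at -1.12 (SE 0.11). Astrocyte transport genes were lower in 7 of 9 and higher in 0 (the same adjusted over the list alone), with GLUL at -1.38 (SE 0.11) and ATP1B2 at -1.33 (SE 0.14). Glycolysis genes were lower in 7 of 12 and higher in 0 (10 and 0 adjusted over the list alone), with ALDOC, an aldolase gene of astrocytes, at -0.91 (SE 0.12). Neuronal differentiation genes were higher in 8 of 12 and lower in 2 (9 and 2 adjusted over the list alone), with DCX at 1.64 (SE 0.24), STMN2 at 1.23 (SE 0.14) and SOX4 at 1.04 (SE 0.10). The mean doublet score was 0.0622 in CRYAB-high and 0.0216 in CLU-high glia. Extracellular matrix genes were lower in 4 of 9 and higher in 2 (4 and 3 adjusted over the list alone), with LAMA1 at -1.80 (SE 0.20) and NCAN at -1.30 (SE 0.13).

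FGF and ERK targets were lower in CRYAB-high glia in 5 of 9 cases and higher in 1 (the same adjusted over the list alone), with SPRY2 at -1.34 (SE 0.15) and ETV5 at -1.11 (SE 0.16). BMP genes were lower in 3 of 9 and higher in 0 (4 and 1 adjusted over the list alone), with ID4 at -0.84 (SE 0.10). Hedgehog genes were higher in 3 of 7 and lower in 1 (4 and 2 adjusted over the list alone), with GAS1 at 0.79 (SE 0.12). Notch genes were higher in 2 of 7 and lower in 2, with RBPJ at 0.81 (SE 0.14) and NOTCH2 at -1.39 (SE 0.13). Wnt genes were lower in 3 of 8 and higher in 0 (4 and 0 adjusted over the list alone), with DKK3 at -1.17 (SE 0.27; -1.82 in library B alone; call ended by DESeq2). YAP and TAZ targets were higher in 1 of 10 and lower in 0, and fatty acid oxidation genes were lower in 1 of 10 and higher in 0. By edgeR and by DESeq2 0 of 7 LIF receptor and STAT3 genes passed the test (1 at an unadjusted p under 0.05 in edgeR), and the smallest p was that of JAK1 (-0.52, adjusted p = 0.0852). Gliogenic transcription factor genes were higher in 2 of 7 and lower in 1 (3 and 2 adjusted over the list alone), with NFIX at 0.81 (SE 0.11) and LHX2 at -0.64 (SE 0.10). Immediate early genes were lower in 3 of 13 and higher in 0 (4 and 0 adjusted over the list alone), with FOS at -0.67 (SE 0.10). The Notch, YAP and TAZ, fatty acid oxidation, and LIF receptor and STAT3 counts were the same adjusted over the list alone.

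No cluster reached a Jaccard index of 0.5 with CRYAB-high glia under the stricter cell filter, the other set of clustering genes, all genes or a resolution of 0.5, and CLU-high glia were not found at a resolution of 2. DESeq2's Wald test called 93 genes higher and 134 lower, with 14 G2 and M phase genes higher and 8 cholesterol genes lower, and the thinned cells gave 72 and 249, with 9 G2 and M phase genes higher.

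The third comparison was between LIFR-high glia (82 and 42 cells) and CLU-high glia. LIFR-high glia held more of GADD45B, a stress-response gene (4.34, SE 0.26, adjusted p = 1.19e-59), JUNB, an immediate early gene (3.35, SE 0.14, adjusted p = 3.91e-115), SLC4A4, a sodium bicarbonate transporter gene of astrocytes (4.004, SE 0.27, adjusted p = 2.75e-44), and HAPLN1, a matrix link protein gene (3.88, SE 0.32, adjusted p = 3.62e-30). SOCS3, a target of STAT3, was higher by a ratio of 138 (44.7 to 687), from 55 UMIs against 3. They held less of NRG3, a neuregulin gene (-3.44, SE 0.18, adjusted p = 2.78e-76), and of GPC5, a glypican gene (-3.41, SE 0.18, adjusted p = 5.55e-75). Of 5285 genes tested, 371 were higher and 454 lower, 248 and 214 of them by more than 2-fold, and 814 of the called genes had the same direction in both libraries.

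Other genes higher in LIFR-high glia were ID3, a BMP target gene (5.96, SE 0.54, adjusted p = 2.25e-25; 4.87 in library A alone), PRUNE2 (5.11, SE 0.44; 3.95 in library B alone) and RARRES1 (4.21, SE 0.36). So were ADAMTS3 (3.93, SE 0.38) and the protocadherin gene PCDH7 (3.80, SE 0.19). Lower were PRR16, by a ratio of 14.9 (5.07 to 72.8), the tetraspanin gene TSPAN15 (-2.90, SE 0.26), CSRP2 (-2.77, SE 0.21), NAPEPLD (-2.70, SE 0.38; -2.05 in library B alone), NRG1 (-2.56, SE 0.20) and the ephrin gene EFNB1 (-2.49, SE 0.21). KCNJ15 was at -3.33 (SE 0.25), with -2.64 in library A alone; library B held 0 KCNJ15 UMIs in LIFR-high glia, so its value of -9.66 is set by the prior count. CCDC85A was at -2.77 (SE 0.34), with -4.10 in library A alone and -1.499 in library B alone, and DESeq2 ended the calls of both KCNJ15 and CCDC85A.

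Immediate early and dissociation response genes were higher in LIFR-high glia in 9 of 13 cases and lower in 0 (9 and 1 adjusted over the list alone), with IER2 at 1.97 (SE 0.14), BTG2 at 1.56 (SE 0.15) and EGR1 at 1.36 (SE 0.12). The mean mitochondrial share was also higher, 1.46% in LIFR-high and 0.814% in CLU-high glia. Of 7 LIF receptor and STAT3 genes 3 were higher and 0 lower, also adjusted over the list alone. They were SOCS3, STAT3 (1.20, SE 0.24, adjusted p = 1.59e-05) and the coreceptor gene IL6ST (0.66, SE 0.22, adjusted p = 0.0232). DESeq2 and the thinned cells ended the calls of STAT3 and IL6ST. BMP genes were higher in 4 of 11 and lower in 2 (the same adjusted over the list alone), with BMP2 at 5.07 (SE 0.63; 4.47 in library A alone and 5.96 in library B alone) and the receptor gene BMPR1B at 1.61 (SE 0.21). FGF and ERK targets were higher in 3 of 10 and lower in 1 (3 and 2 adjusted over the list alone), with ETV4 at 3.88 (SE 0.55) and DUSP6 at 3.01 (SE 0.44; 3.99 in library A alone and 1.098 in library B alone). Hedgehog genes were lower in 3 of 6 and higher in 0, with GLI2 at -1.25 (SE 0.20), a call that DESeq2 ended. Notch genes were lower in 2 of 7 and higher in 1, with NOTCH2 at -1.80 (SE 0.17) and HEY1 at -0.85 (SE 0.25; -1.87 in library B alone; call ended by DESeq2). Wnt genes were higher in 3 of 10 and lower in 3 (5 and 4 adjusted over the list alone), with WNT5A at 3.27 (SE 0.64) and SFRP1 at -1.37 (SE 0.15). YAP and TAZ targets were higher in 2 of 10 and lower in 1, with CCN1 at 1.30 (SE 0.22). The hedgehog, Notch, and YAP and TAZ counts were the same adjusted over the list alone.

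As in CRYAB-high glia, cholesterol synthesis genes were lower, in 11 of 15 cases with 0 higher (13 and 0 adjusted over the list alone), with SC5D at -1.22 (SE 0.19) and FDPS at -1.07 (SE 0.14). Likewise, G2 and M phase genes were higher in 17 of 18 cases and lower in 0 (the same adjusted over the list alone), with CENPE at 2.51 (SE 0.32) and CENPF at 2.15 (SE 0.22). Both comparisons used the same CLU-high cells, so their results are not independent, and the unnamed mitotic cluster was left out of both. S phase genes were lower in 2 of 17 and higher in 1 in LIFR-high glia. Extracellular matrix genes were higher in 4 of 11 and lower in 2, with the collagen gene COL4A1 at 3.12 (SE 0.51). Astrocyte transport genes were higher in 2 of 10 and lower in 2 (2 and 3 adjusted over the list alone), with FXYD1 at 1.42 (SE 0.21) and SLC38A3 at -1.74 (SE 0.26; -1.15 in library B alone). Neuronal differentiation genes were higher in 2 of 12 and lower in 3 (4 and 3 adjusted over the list alone), with ELAVL4 at 2.02 (SE 0.31) and ROBO1 at -1.74 (SE 0.15). Gliogenic transcription factor genes were higher in 2 of 7 and lower in 1 (3 and 2 adjusted over the list alone), with LHX2 at -1.24 (SE 0.14). Glycolysis genes were lower in 2 of 12 and higher in 1, with ALDOC at -1.12 (SE 0.14). By edgeR and by DESeq2 0 of 10 fatty acid oxidation genes passed the test (1 at an unadjusted p under 0.05 in edgeR), and the smallest p was that of ACAA2 (-0.65, adjusted p = 0.0549). The S phase, extracellular matrix, glycolysis and fatty acid oxidation counts were the same adjusted over the list alone. DESeq2's Wald test called 117 genes higher and 86 lower, with 9 G2 and M phase genes higher and 4 cholesterol genes lower. The thinned cells gave 92 and 177, with 4 G2 and M phase and 5 cholesterol genes, and the comparison was not possible at a resolution of 0.5, where no cluster matched LIFR-high glia, or of 2, where none matched CLU-high glia.

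The last comparison set oligodendrocyte precursor-like cells (152 and 60 cells) against gliogenic progenitor-like cells. The first class also carried the markers of committed oligodendrocytes, so its differences may not be those of precursors alone. Its cells held more POSTN, the gene of the matrix protein periostin, by a ratio of 391 (69.5 to 15522) from 231 UMIs against 1. Also higher in these cells were CHRM3, a muscarinic receptor gene (6.63, SE 0.27, adjusted p = 4.13e-11), and TNR, the gene of tenascin R (5.18, SE 0.19, adjusted p = 1.38e-11). They held less IGFBP5 (-5.37, SE 0.21, adjusted p = 2.32e-11; -6.06 in library B alone) and less GAS1, a hedgehog coreceptor gene (-3.17, SE 0.15, adjusted p = 1.93e-10). Of 4508 genes tested, 644 were higher and 810 lower in oligodendrocyte precursor-like cells, 426 and 357 of them by more than 2-fold, and 1449 of the called genes had the same direction in both libraries.

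Other genes with few UMIs in gliogenic progenitor-like cells were higher by ratios of 237 for SCIN (41.9 to 9433), 141 for TMEM132C (24.5 to 5619), 84.7 for MEGF11 (22.8 to 709), 64.4 for the matrilin gene MATN4 (17.2 to 541) and 41.2 for KANK1 (13.6 to 204.5). IGFBP7 was higher by 5.56 (SE 0.25, adjusted p = 1.52e-10), with 6.17 in library A alone and 4.64 in library B alone, and the endophilin gene SH3GL3 by 5.53 (SE 0.38; 4.17 in library B alone). Lower were the polarity gene PARD3B (-3.93, SE 0.33), CHRDL1, the gene of a BMP antagonist (-3.69, SE 0.43), EFHD2 (-3.19, SE 0.24; -3.81 in library B alone), RBMS3 (-3.18, SE 0.28) and TGIF1 (-3.16, SE 0.40). So were BTG2 (-2.90, SE 0.28; -3.79 in library B alone), ADAMTS6 (-2.67, SE 0.24) and GLI2 (-2.57, SE 0.29; -1.94 in library B alone).

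**Figure D3:**
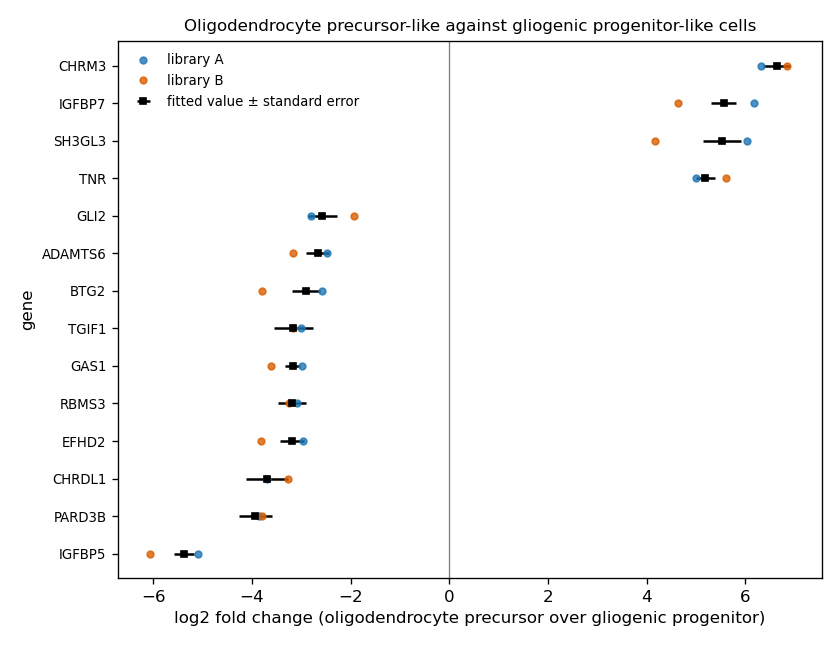
Log2 fold change of 14 genes in oligodendrocyte precursor-like over gliogenic progenitor-like cells; black squares are fitted values with their standard error, blue and orange points are libraries A and B. Genes with 1 to 3 UMIs in the lower class are not drawn; CHRM3 lies highest at 6.63 and IGFBP5 lowest at -5.37.

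Cell cycle genes were lower in oligodendrocyte precursor-like cells: 22 of 22 G2 and M phase genes and 16 of 19 S phase genes fell and 0 rose (22 and 18 lower adjusted over the list alone). TOP2A was at -1.70 (SE 0.13) and UBE2C at -1.32 (SE 0.13). RRM2 was at -1.69 (SE 0.14) and PCNA at -1.45 (SE 0.13). With a resolution of 2 the G2 and M phase count was instead 2 higher and 0 lower, and UBE2C came to 0.49. Gliogenic transcription factor genes fell in 6 of 7 cases and rose in 1 (the same adjusted over the list alone), with ZBTB20 at -1.22 (SE 0.09), NFIA at -1.15 (SE 0.08, adjusted p = 2.26e-08) and NFIX at -1.01 (SE 0.13). Hedgehog genes fell in 5 of 6 and rose in 0, with GAS1, GLI2, CDON (-1.69, SE 0.23) and SMO (-2.42, SE 0.47; -1.81 in library A alone and -3.70 in library B alone; call ended by DESeq2). Notch genes fell in 4 of 6 and rose in 0, with LFNG at -2.59 (SE 0.47) and NOTCH2 at -1.92 (SE 0.41; -1.31 in library B alone), and DESeq2 ended the calls of LFNG and NOTCH2. The hedgehog and Notch counts were the same adjusted over the list alone. YAP and TAZ targets fell in 3 of 6 and rose in 0, also adjusted over the list alone, with TEAD1 at -2.02 (SE 0.19), TEAD2 lower by a ratio of 36.0 (6.22 to 1445) and YAP1 at -1.43 (SE 0.35; -0.83 in library B alone; call ended by DESeq2). Immediate early genes fell in 6 of 9 and rose in 0 (8 and 0 adjusted over the list alone), with IER2 at -1.28 (SE 0.14).

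Extracellular matrix genes rose in 5 of 8 cases and fell in 1 in oligodendrocyte precursor-like cells, with BCAN at 2.75 (SE 0.14, adjusted p = 3.48e-10), CSPG5 at 2.41 (SE 0.20; 1.71 in library B alone) and COL11A1 at 2.12 (SE 0.15). HAPLN1 rose by 4.60 (SE 0.50), with 3.70 in library A alone; library B held 0 HAPLN1 UMIs in gliogenic progenitor-like cells, so its value of 6.92 is set by the prior count. FGF and ERK targets went both ways, 3 of 11 higher and 3 lower, with SPRY4 at 3.28 (SE 0.47), CCND1 at 1.71 (SE 0.17) and ETV1 at -1.08 (SE 0.14). BMP genes rose in 2 of 8 and fell in 2 (2 and 4 adjusted over the list alone), with BMP4 higher by a ratio of 28.8 (7.38 to 247) and ID1 at -2.04 (SE 0.19). Wnt genes rose in 2 of 8 and fell in 2 (2 and 3 adjusted over the list alone), with TCF7L2 at 1.98 (SE 0.18). Neuronal differentiation genes rose in 5 of 13 and fell in 3 (5 and 4 adjusted over the list alone), with MYT1L at 3.08 (SE 0.28), ROBO1 at 2.50 (SE 0.15), MYT1 at 1.59 (SE 0.18) and SOX4 at -0.78 (SE 0.07). The mean doublet score was 0.0742 in oligodendrocyte precursor-like and 0.043 in gliogenic progenitor-like cells. Astrocyte transport genes rose in 2 of 5 and fell in 1, with GLUL at -1.08 (SE 0.15) and ATP1B2 at 1.81 (SE 0.37; 3.02 in library B alone). ATP1B2 came to -1.37 with a resolution of 0.5, and DESeq2 ended its call. Cholesterol synthesis genes rose in 2 of 14 and fell in 0. Fatty acid oxidation genes fell in 2 of 8 and rose in 0, with ACAA2 at -1.78 (SE 0.32) and HADH at -1.45 (SE 0.29; -0.79 in library B alone). DESeq2 ended the calls of ACAA2 and HADH. Glycolysis genes rose in 2 of 12 and fell in 1, with LDHB at -0.69 (SE 0.07). Of 5 LIF receptor and STAT3 genes 0 rose and 1 fell, CNTFR (-1.09, SE 0.34, adjusted p = 0.0208), a call that DESeq2 ended. The extracellular matrix, FGF and ERK, astrocyte transport, cholesterol, fatty acid oxidation, glycolysis, and LIF receptor and STAT3 counts were the same adjusted over the list alone. DESeq2's Wald test called 215 genes higher and 160 lower, with 9 G2 and M phase and 5 S phase genes lower, and the thinned cells gave 255 and 361, with 11 and 9.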

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

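Added only after the clusters had been seen were the comparisons of CRYAB-high and LIFR-high with CLU-high glia, the removal of cells with a doublet score above 0.2, the neuronal intermediate progenitors of the dividing compartment only, the gene counts with no cell filter and at a resolution of 0.5, the named genes with no low-count filter, the other clusterings as tests of named genes, and every alternative for the lists. The cause of each change below was not tested, except that thinning leaves fewer UMIs to count and that the resolution sets the number of clusters. The kept doublet adds only 1 cell, so the changes under that setting come through clusters that were drawn differently. The depth limits the class comparisons most for LIFR-high glia, with 82 and 42 cells.

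The number of genes called higher and lower moved by more than 1.5 times in these cases. DESeq2's Wald test called 245 and 265 genes in gliogenic against neuronal intermediate progenitors, 93 and 134 in CRYAB-high against CLU-high glia, 117 and 86 in LIFR-high against CLU-high glia, and 215 and 160 in oligodendrocyte precursors against gliogenic progenitors. With every cell thinned to 1500 UMIs these counts were 266 and 442, 72 and 249, 92 and 177, and 255 and 361. The dividing compartment only gave 619 lower genes in the first comparison, the kept doublet 591 higher genes in the CRYAB-high comparison, and the other set of clustering genes 301 lower genes in the LIFR-high comparison. That set also replaces most tested genes: 185 of the 5285 tested in the LIFR-high comparison were tested in both. With no replicate block the 4 comparisons gave 616 and 771, 241 and 406, 380 and 449, and 618 and 733, all within 1.5 times. With DESeq2 size factors in edgeR 79 of 79, 69 of 69, 69 of 72 and 74 of 75 named calls kept their direction and their side of the threshold, and with DESeq2's Wald test 57 of 79, 48 of 69, 45 of 70 and 54 of 75 did. Of the 34 list counts per comparison, DESeq2's Wald test moved 16, 14, 20 and 17 by more than 1.5 times and thinning 14, 14, 21 and 16; a resolution of 0.5 moved 20 in the first and 16 in the last comparison and a resolution of 2 moved 9 and 10. In the first comparison the dividing compartment only moved 14, all genes 11, the kept doublet 11 and the other set 10, and in the LIFR-high comparison no filter and the other set moved 8 each; all other settings moved 7 or fewer.

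Mean class shares of the 2 libraries that moved by more than the spread between them were these. CLU-high glia (7.20%) took 5.45% with no cell filter, 6.28% with the stricter filter, 4.15% with all genes and 8.61% at a resolution of 0.5. CRYAB-high glia (1.94%) took 1.60% with no filter, 2.96% with the doublet kept and 1.51% at a resolution of 2. LIFR-high glia (0.840%) took 0.930% with no filter, 0.952% with the stricter filter, 0.830% with the doublet kept, 0.881% with the other set, 0.728% with all genes, 0.744% at a resolution of 2 and 0.957% without cells of a score above 0.2. Neuronal intermediate progenitors (16.8%) took 18.4% with the stricter filter, 11.99% with the doublet kept, 10.4% with the other set, 10.5% with all genes, and 15.0% and 7.58% at resolutions of 0.5 and 2. Excitatory neurons (42.4%) took 35.9% with the other set, 37.1% with all genes and 47.3% at a resolution of 0.5. Gliogenic progenitors (2.58%) took 2.28% with all genes and 1.82% at a resolution of 2, where erythroid cells (2.86%) took 1.01% and microglia (0.525%) 3.02%.

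Over all genes, the first comparison changed most. Of its called genes that were also fitted there, 150 of 1655 had the opposite sign at a resolution of 0.5 (61 of them called), 181 of 1561 with the dividing compartment only (51 called) and 75 of 1616 with all genes (14 called), while 1051, 752 and 1053 were called in the same direction. With the other set 7 of 99 had the opposite sign (3 called) and 75 were called in the same direction; the other called genes were not tested there. In the last comparison 35 of 1441 had the opposite sign at a resolution of 0.5 (9 called) and 28 of 1419 at a resolution of 2 (4 called).

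Among the named genes, log2 fold changes reversed for these. In gliogenic against neuronal intermediate progenitors, a resolution of 0.5 gave ACADVL 0.0070, AURKB -0.80, CLSPN -0.42, MKI67 -0.99, PCNA -0.077, PIAS3 0.070, TOP2A -0.80, TPI1 0.0023, TYK2 0.55 and TYMS -0.29. The dividing compartment only gave AURKB -0.61, CLSPN -0.37, ID1 -0.37, MCM3 -0.088, MKI67 -0.66, PCNA -0.27, SFRP1 -0.061, TOP2A -0.66 and TYMS -0.34. All genes gave AURKB -0.41, CLSPN -0.11, MKI67 -0.61, TOP2A -0.44, TYK2 0.19 and TYMS -0.051, and the other set AURKB -0.58, MKI67 -0.68, TOP2A -0.60 and TYK2 0.43. The kept doublet gave AURKB -0.20, MKI67 -0.20 and TOP2A -0.22, and removal of scores above 0.2 gave TYK2 0.074. In the CRYAB-high comparison the kept doublet gave PCNA 0.51, TYK2 0.12 and TYMS 0.22, and thinning gave HADHA 0.043 and JAK2 -0.082. In oligodendrocyte precursors against gliogenic progenitors, a resolution of 0.5 gave ATP1B2 -1.37, CPT1A -0.20, DHCR7 -0.22, HMGCS1 -1.06, IL6ST -0.30, STAT3 -0.72 and TCF7L1 -0.0054, and a resolution of 2 gave CCNB2 0.21, NUSAP1 0.052 and UBE2C 0.49.

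Without 1 library there is no residual spread, so values were taken with no test; CDC20 then ranged from -0.59 to 0.051 in the first comparison and was the only called value among the named genes that changed sign. The comparison of CRYAB-high with CLU-high glia was not possible under the stricter filter, the other set, all genes, and resolutions of 0.5 and 2, nor that of LIFR-high with CLU-high glia at resolutions of 0.5 and 2, since a cluster was not found again. The kept doublet adds 1 cell, yet the nearest cluster to CRYAB-high glia then shared a Jaccard index of 0.583 with it.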

Other observations

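The test of mural-like cells, the test of doublets partner by partner and the test of DLX5, DLX6, GAD1 and GAD2 were chosen only after the result was seen, as were the retained part over all 816 called genes and the counting of the 6 clusters with few cells or a high doublet score; the other 4 tests were written down before.

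The summed RNA of the fixed lists also set apart classes that no comparison covered; these values, over the 11 classes with at least 20 cells in each library, were not tested. Cholesterol synthesis genes reached 4025 CPM in library A and 4030 CPM in library B in CLU-high glia and 2402 and 2724 CPM in LIFR-high glia, against 818 and 899 CPM in excitatory neuron-like cells and 581 and 679 CPM in inhibitory neuron-like cells. BMP signalling genes were also most abundant in CLU-high glia (3306 and 3240 CPM), followed by LIFR-high glia (2700 and 3053 CPM), against 516 and 464 CPM in gliogenic progenitor-like cells. FGF and ERK targets stood at 914 and 934 CPM in gliogenic progenitor-like cells and 933 and 906 CPM in oligodendrocyte precursor-like cells. They were nearly as high in LIFR-high glia (837 and 787 CPM) and CLU-high glia (814 and 726 CPM), against 257 and 249 CPM in neuronal intermediate progenitor-like cells. Immediate early genes were highest in microglia-like cells (9887 and 7908 CPM), followed by LIFR-high glia (6653 and 6293 CPM), and stood at 713 and 855 CPM in inhibitory neuron-like cells. YAP and TAZ targets stood at 937 and 782 CPM in endothelial-like cells and 700 and 753 CPM in LIFR-high glia. Matrix genes stood at 2111 and 1996 CPM in endothelial-like, 2051 and 2080 CPM in oligodendrocyte precursor-like cells and 1931 and 1937 CPM in LIFR-high glia.

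Endothelial-like cells took a larger share of library B than of library A, by a ratio of 5.05 (counting interval 4.07 to 6.28). The lower depth of library B as its whole cause is argued against by cells with at least 3000 UMIs, where the ratio was 5.37 (3.10 to 9.43; 38 of 6919 cells in library A and 77 of 2613 in library B). More vessel tissue of every kind in library B cannot be told apart from endothelial-like cells alone, because the mural-like ratio was 1.26 (0.343 to 4.37) on 14 and 9 cells. In addition, 5 of 5 mural markers were higher in the endothelial-like cluster (mean log2 ratio 2.682). Mural cells may thus be counted there, and the mural-like cells may not measure all mural tissue. Ependymal-like cells also differed, by a ratio of 15.0 (5.06 to 54.5), so a difference in the tissue that was dissected stays open and was not tested. With 1 group of 2 libraries, no biological explanation was tested.

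LIFR-high glia held more immediate early RNA than CLU-high glia, by 0.94 on the log2 scale for the summed list. For a dissociation response as the whole difference between the clusters, LIFR-high glia were set against CLU-high cells matched on that RNA (57 and 41 cells). Matching brought the summed list to -0.21 and the median over the list genes from 0.98 to 0.14. The other 455 genes called at 2-fold or more retained a median of 1.07 of their difference (1.04 and 1.07 in the 2 libraries). All 816 other called genes retained a median of 1.06. CLU-high cells with as much immediate early RNA thus did not share the other differences. The clustering had already placed these matched cells in CLU-high glia. Cells whose other genes had changed with the response could have been placed in LIFR-high glia. The matching therefore cannot decide whether a dissociation response made the difference. Of the called genes at 50 CPM or more, 8 lay 2-fold or more above every other cluster, fewer than the 10 set beforehand against doublets of CLU-high glia with cells of another cluster. That test therefore did not decide. A doublet of average cells lies between its parents. For each of the 26 partner clusters, at least 67 of 225 called genes lay above both parents. Their lower counting bounds were above the upper bounds of CLU-high glia and of that cluster. Above all clusters at once lay 13 genes, among them OGN, TMEM100 and CITED1. The 225 genes had been called higher than CLU-high glia in these same cells, and the bounds cover counting error only. The values thus argue against doublets with average cells of 1 cluster, but not against doublets with part of a cluster. Doublets with a kind of cell that formed no cluster were not tested (mean doublet score 0.0620 in LIFR-high and 0.0216 in CLU-high glia), the part of the immediate early RNA that the tissue held before dissociation stays open, and no biological explanation was tested.

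Gliogenic progenitor-like cells held GSX2, DLX1 and DLX2 RNA. Inhibitory neurons in doublets or as free RNA are argued against by DLX5, DLX6, GAD1 and GAD2, which together stood at 0.0667 of the level that the DLX1 level and the inhibitory profile give (24.3 against 370 CPM in library A and 21.6 against 319 CPM in library B, upper counting bound 0.118). Whether separate cells with OLIG1 and with GSX2, DLX1 or DLX2 share 1 cluster was not settled, because the ratios lay close to the cut of 0.5. OLIG1 was less frequent in cells with GSX2, DLX1 or DLX2 than in the others in both libraries (upper counting bounds 0.719 and 0.861). Part of the cells with GSX2, DLX1 or DLX2 still held OLIG1. After thinning, the share of cells with an OLIG1 UMI among cells with GSX2, DLX1 or DLX2 over that among the others was 0.497. It was 0.4993 and 0.4951 in the libraries, under the 0.5 written down before for separate cells. That rule named no counting bounds, while the rule written against separate cells asked for a lower bound above 0.5. The counting bounds of 0.259 and 0.861 lie on both sides of 0.5. The rule against separate cells was therefore not met, and the ratio is not clearly under 0.5. The shares with an OLIG1 UMI were 36.4% of 88 and 72.8% of 184 cells in library A. In library B they were 35.9% of 39 and 72.5% of 80 cells. Before thinning, OLIG1 was seen in 53.0% and 86.4% of library A and 54.2% and 90.0% of library B, against 1.57% and 0.929% of inhibitory neuron-like cells, at median depths of 4673.5 and 4099 UMIs in gliogenic progenitor-like and 2879.5 and 2579 UMIs in inhibitory neuron-like cells; no biological explanation was tested.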
